A study of Mus musculus with 60 samples.

How the data were processed

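Total RNA labelled with biotin was measured on Illumina mouse BeadChips, which carry 6 arrays each. The wild-type macrophage experiment held 12 arrays on 3 chips, the macrophage experiment with both labelled genotypes 36 arrays on 6 chips and the carotid artery experiment 12 arrays on 2 chips. Macrophages were grown for 6 d with 40 ng/ml M-CSF. The growth protocol names 6 to 8 week old wild-type C57BL/6 mice, and the source of the bone marrow labelled Atf3-deficient is not described beyond the genotype and a strain label of C57BL/6. The numbers of the replicates follow the order of the records and pair no arrays across groups.

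The deposited scanner tables hold, per the file headers, a mean signal intensity for each probe and array and a detection p-value for each probe and array. From the values, the intensities are on a linear scale, were not normalised between arrays and still contain the background. The deposited matrix holds a normalised intensity for the macrophage arrays, on a linear scale and with equal quartiles within each experiment (medians of 96.5 and 113.9), and log2 of the un-normalised signal for the artery arrays (medians from 6.72 to 6.96). The submitters' processing notes name Partek, without a version, and do not state its steps. The lowest Spearman correlation between an array's signals and its matrix values was 0.99998. How RNA was extracted and which scanner software was used are not stated.

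Of 45281 probes, 34885 were paired with 1 gene symbol, 18 with several and 10378 with none, and 34807 were found in the reference table of gene names by their identifier. They covered 19057 genes, of which 9172 had more than 1 probe; the probe with the highest mean signal was used, and both macrophage experiments used the same one. The named genes Il12b and Hmgcs1 had no matching symbol and were not analysed here, and Ifit1 and Abca1 were not detected on enough arrays to be tested. Positions of probes in genes or in the genome are not given, so none are printed.

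Each experiment was processed on its own with limma 3.58.1 in R 4.3.3. Background was corrected with neqc, which fits normexp from the detection p-values, adds an offset of 16, quantile normalises the arrays and takes log2. Genes whose probe had a detection p under 0.01 on at least 3 arrays of the experiment were tested, 8991, 9204 and 9353 in the 3 experiments. One linear model with a mean for each group was fitted per experiment, with 8, 24 and 8 residual degrees of freedom, and moderated by eBayes. Each comparison is a contrast of group means, and a difference between labelled genotypes or between responses is the contrast of both differences. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested in that comparison. A gene is called not above background in a group where its probe was detected on none of the group's arrays. Its fold is then given as a lower bound. On each of those arrays the higher of its signal and the lowest signal of any detected probe was taken, and the group mean of these values was used. No fold is given where a gene was not above background in both groups or in part of a difference. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

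A total of 27 gene lists, of inflammatory, interferon, lipid and stress pathways and of cell type markers, were tested with camera at a preset correlation between genes of 0.01, and again with the correlation estimated, adjusting over the lists of a comparison; p-values beside a list in the results are these adjusted values. For no list that passed did the median, the mean and the test differ in sign. Genes that rose at least 2-fold with CpG in one experiment were followed as a set in arrays of other experiments, 10 results adjusted together. The named genes were Atf3, 16 genes followed where their group is described, the 5 largest rises and falls among genes that passed (the 3 smallest p where none did) and the 4 members with the largest change in each list, leaving out symbols that are only clone names. Groups, comparisons, the tests of these comparisons, lists, the rule for named genes and the alternatives other than 3 were fixed before the data were examined. Those 3 leave out artery arrays of low signal, leave out artery arrays with the Erdr1 signal of the other label, and weight arrays by quality.

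The alternatives were no normexp correction (values under 16 set to 16), median scaling in place of quantile normalisation, the deposited matrix values, no detection filter, the chip as a fixed effect or as a random effect, only the groups compared in the model, and leaving out each array in turn. The correlation between arrays of a chip was 0.41, 0.0962 and -0.0364 in the 3 experiments. Where 1 or more chips held all groups of a comparison, it was also computed within those chips; where none did, the value is that of the model with the chip as a fixed effect, or no value is given.

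Detected probes per array ranged from 12209 to 15323 in the wild-type macrophages, from 11951 to 14785 in the macrophages of both labels and from 9266 to 15397 in the arteries, and median signals from 93.6 to 101.3, from 91 to 149.2 and from 105.3 to 124.1. The model fits and set tests were tried on simulated data with the number of these arrays and the spread of each gene. In these data 100 genes were changed by a log2 fold of 1 and 100 by 2. The noise was independent between genes and arrays, so chip effects, arrays of low signal and correlation between genes were not simulated. For HDL before CpG, 62 and 95 were recovered in the first experiment and 85 and 99 in wild-type cells of the second; for the labels in control cells, 86 and 100; for HDL in the artery, 22 and 69 in wild-type and 23 and 62 in arteries labelled Atf3-deficient. False calls numbered 1 to 14.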

Results

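Gene expression was measured on 60 Illumina mouse BeadChip arrays from 3 experiments on high-density lipoprotein (HDL), the plasma lipoprotein that takes up cholesterol from cells, and on the stress-induced transcription factor ATF3. The first experiment held 12 arrays of wild-type bone marrow-derived macrophages in 4 groups of 3: control, CpG, HDL, and HDL followed by CpG. CpG is DNA that stimulates the receptor TLR9. The second held 36 arrays in 12 groups of 3, with wild-type macrophages and macrophages labelled Atf3-deficient, each as control, CpG, P3C, HDL, HDL with CpG and HDL with P3C. P3C is a stimulus of TLR2. HDL was given at 2 mg/ml for 6 h before 4 h of ligand, with CpG at 100 nM and P3C at 50 ng/ml. The third held 12 arrays of injured carotid artery in 4 groups of 3. These came from wild-type mice and mice labelled Atf3-deficient that received HDL at 20 mg/kg or PBS 3 h after the injury, with a stimulation period of 12 h. The labels do not say whether arrays of a group came from separate animals or cultures. Between 26.4% and 33.8% of the 45281 probes were detected on each macrophage array and between 20.5% and 34.0% on each artery array. With 3 arrays per group, their number limits the precision. Changes are log2 fold changes ± SE from limma over 3 arrays per group. "Rose" and "fell" mean an adjusted p under 0.05, and "at least" marks a gene whose signal in one group was not above background.

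The probe for Atf3 was examined first and detected on all 3 arrays of every group. In the first experiment its log2 signal was 9.97 ± 0.525 (SD, n = 3) in control cells, 9.89 ± 0.175 with CpG, 10.97 ± 0.0818 with HDL and 10.86 ± 0.299 with HDL and CpG. HDL raised it by 1.0 ± 0.24 over control and by 0.96 ± 0.24 over CpG. CpG alone did not pass (-0.07 ± 0.24, adjusted p = 0.847). The wild-type groups of the second experiment gave 11.20 ± 0.081 (control), 10.85 ± 0.218 (CpG), 11.18 ± 0.275 (P3C), 11.86 ± 0.257 (HDL), 11.92 ± 0.0975 (HDL and CpG) and 12.15 ± 0.0507 (HDL and P3C). HDL raised Atf3 there by 0.66 ± 0.17 over control, 1.07 ± 0.17 over CpG and 0.97 ± 0.17 over P3C. The groups labelled Atf3-deficient gave higher signals, 12.68 ± 0.277, 12.24 ± 0.383, 11.88 ± 0.21, 13.23 ± 0.135, 12.85 ± 0.0648 and 13.24 ± 0.129 in the same order. Control cells of this label exceeded wild-type control cells by 1.47 ± 0.17. HDL raised the signal in these cells too, by 0.55 ± 0.17, 0.62 ± 0.17 and 1.36 ± 0.17 over control, CpG and P3C. Within the chips with both control groups, cells labelled Atf3-deficient were higher by 1.71 and 1.09. The position of the probe in the gene is not given. A probe outside a deleted part would measure the rest of the transcript and would not test the label. Injured arteries had Atf3 signals of 7.37 ± 1.3 (PBS) and 8.80 ± 1.28 (HDL) in wild-type. Those labelled Atf3-deficient had 9.12 ± 0.556 and 8.67 ± 2.01 in this order. No artery comparison of Atf3 passed. HDL effects were 1.43 ± 0.98, adjusted p = 0.355 in wild-type and -0.44 ± 0.98, adjusted p = 1 in the other label. The negative sign rests on HDL replicate 3 (6.35), with 0.64 and -2.61 within chips.

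**Figure D1:**
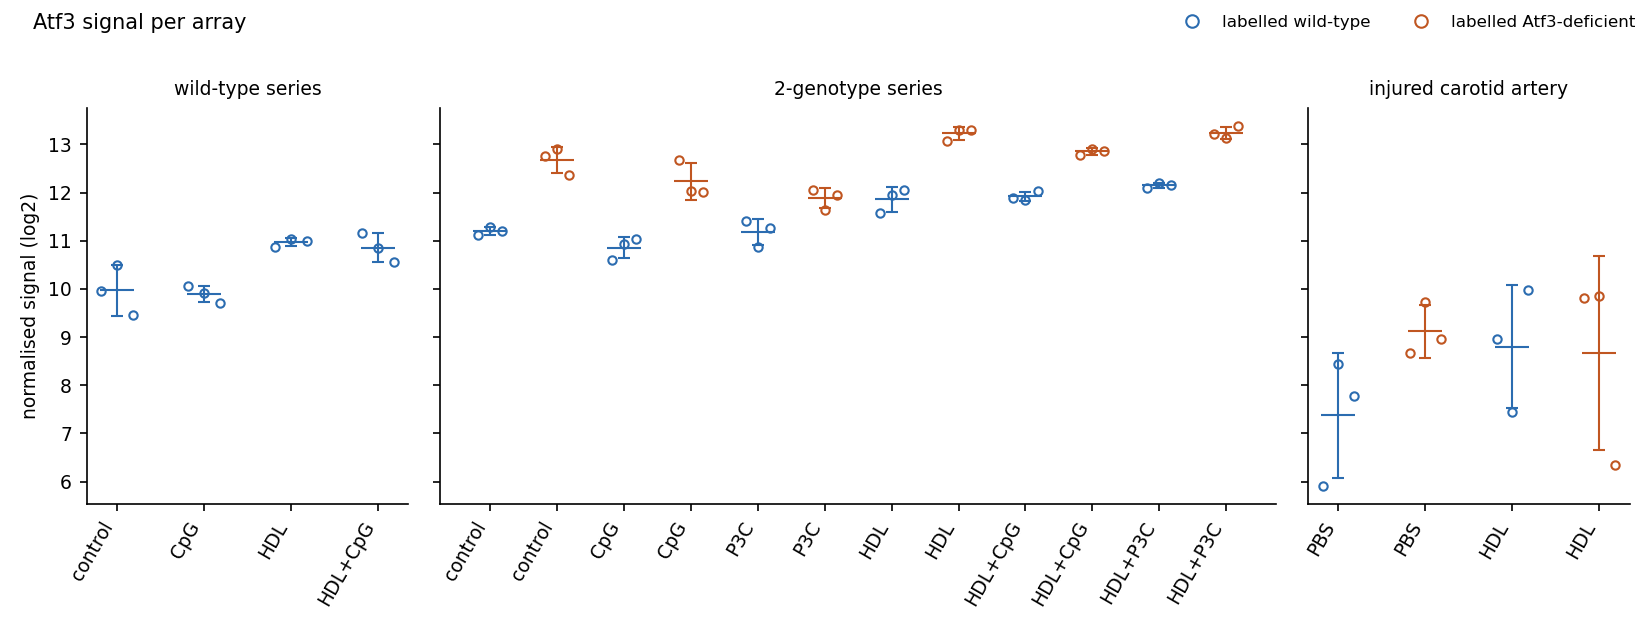
Log2 signal of the Atf3 probe on each array (open circles) with the group mean (dash) and SD (bar), 3 arrays per group, for both macrophage experiments and the injured artery. The macrophage groups labelled Atf3-deficient, with means from 11.88 to 13.24, lie above the wild-type groups of the same treatment, and macrophage HDL groups lie above their controls. In arteries labelled Atf3-deficient the HDL group (8.67) lies below PBS (9.12).

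CpG set off a broad inflammatory response in the wild-type macrophages of the first experiment. The largest rises were those of Socs3, a feedback inhibitor of cytokine signalling (6.33 ± 0.16), Acod1, the enzyme that makes itaconate (6.13 ± 0.27), the neutrophil-attracting chemokine Cxcl2 (6.08 ± 0.37), the acute phase protein Saa3 (6.08 ± 0.15) and the niacin receptor Hcar2 (5.82 ± 0.22). Among the cytokines, Il1b rose by 5.36 ± 0.29, Tnf by 5.27 ± 0.26 and Il10, which restrains inflammation, by 4.48 ± 0.20. Il6 rose at least 4.45-fold (adjusted p = 0.000803). Of 11 inflammatory cytokines measured, 9 rose, 0 fell and 2 did not pass, or 10 up and 1 down adjusted over the list alone. Their median was 2.23 (adjusted p = 1.83e-09). Chemokines included Ccl5 (3.96 ± 0.20) and Cxcl10 (3.77 ± 0.21). Of 16, 13 rose and 1 fell, by either count (adjusted p = 7.49e-13). All 22 NF-kB feedback and target genes measured rose by either count, with a median of 2.36 (adjusted p = 2.31e-21). Interferon-stimulated genes, such as Ifi205 (3.37 ± 0.18) and Usp18 (2.74 ± 0.24), rose in 14 of 30 cases, 0 fell and 16 did not pass, or 15 up and 0 down adjusted over the list alone. Their median was 0.69 (adjusted p = 8.23e-09; adjusted p = 0.131 with an estimated correlation). The largest falls were those of Lpar6, a lysophosphatidic acid receptor (-4.43 ± 0.25), Cytip (-4.31 ± 0.18), Tmem86a (-3.92 ± 0.19) and, by at least 14.1-fold and 11.9-fold, the chemokine receptor Cxcr4 and Fam214a (adjusted p = 1.16e-05 and 3.04e-08). Abcg1, which exports cholesterol to HDL, fell too (-1.97 ± 0.19). In all, 3052 of 8991 genes passed, 1147 up and 1905 down. On the chips that held both groups the cytokine medians were 2.21 and 2.27.

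HDL alone raised genes of cholesterol synthesis and of oxidant defence in these cells. The largest rises were those of the cystine transporter Slc7a11 (3.19 ± 0.22), of the cholesterol synthesis enzymes Mvd (2.91 ± 0.24), Cyp51 (2.88 ± 0.33) and Lss (2.75 ± 0.21), and of the heparan sulfate-cleaving enzyme Hpse (2.77 ± 0.28). Of 18 genes of sterol synthesis and uptake, targets of the transcription factor SREBP2, 14 rose, 0 fell and 4 did not pass, or 16 up and 0 down adjusted over the list alone. Their median was 1.86 (adjusted p = 1.42e-22). NRF2 targets of the antioxidant response included the glutathione transferase Gsta3 (2.75 ± 0.26) and sulfiredoxin Srxn1 (1.78 ± 0.21). Of 15, 6 rose and 0 fell, or 9 up and 0 down adjusted over the list alone (adjusted p = 3.92e-09). ATF4 targets of the integrated stress response, such as Chac1 (2.39 ± 0.25) and Trib3 (1.91 ± 0.19), rose in 6 of 20 cases and fell in 0, or 8 up and 0 down adjusted over the list alone. This list had an adjusted p = 1.31e-06 and an adjusted p = 0.0755 with an estimated correlation. Interferon-stimulated genes moved the other way, with 17 of 30 falling, 0 rising and 13 not passing, or 0 up and 21 down adjusted over the list alone. Their median was -1.20 (adjusted p = 8.89e-16), with Cmpk2 at -2.18 ± 0.20, Ifit3 at -2.17 ± 0.26 and Rsad2 at -1.82 ± 0.22. NF-kB targets fell in 8 of 22 cases and rose in 0, or 0 up and 10 down adjusted over the list alone (adjusted p = 2.59e-07). The largest falls were those of Gpr84, a receptor for medium-chain fatty acids (-3.41 ± 0.13), the fractalkine receptor Cx3cr1 (-3.23 ± 0.18), the formyl peptide receptor Fpr2 (-2.93 ± 0.14), the NF-kB cofactor Nfkbiz (-2.85 ± 0.16) and Btbd11 (-2.70 ± 0.23). Tnf (-1.10 ± 0.26), Il10 (-1.77 ± 0.20) and Abcg1 (-2.60 ± 0.19) fell as well. HDL changed 722 genes, 288 up and 434 down, and 395 passed without HDL replicate 2 and 333 with only the groups compared in the model. On the single chip with both groups the sterol and interferon medians were 1.56 and -1.50, and with the chip in the model 1.67 and -1.44.

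HDL before CpG lowered interferon-stimulated genes, while Tnf, Il6 and Il1b did not pass the test. Compared with CpG alone, the largest falls were those of Fcgr1, the high-affinity IgG receptor (-3.34 ± 0.20), the monocyte-attracting chemokine Ccl12 (-3.33 ± 0.19), Usp18, which removes ISG15 from proteins (-3.15 ± 0.24), the antiviral GTPase Mx2 (-2.78 ± 0.19) and Il10 (-2.55 ± 0.20). Of 30 interferon-stimulated genes, 22 fell, 0 rose and 8 did not pass, or 0 up and 24 down adjusted over the list alone. Their median was -1.44 (adjusted p = 1.25e-18). Values short of the threshold were those of Tnf (-0.07 ± 0.26, adjusted p = 0.897), Il6 (-0.18 ± 0.46, adjusted p = 0.85), Il1b (-0.85 ± 0.29, adjusted p = 0.0963), Ccl5 (-0.47 ± 0.20, adjusted p = 0.193) and the prostaglandin-forming enzyme Ptgs2 (1.67 ± 0.67, adjusted p = 0.163). Il27 fell (-1.04 ± 0.19) and Osm rose (0.86 ± 0.19). Of 11 cytokines, 1 rose, 3 fell and 7 did not pass, or 1 up and 4 down adjusted over the list alone. The cytokine list had an adjusted p = 0.0347 and an adjusted p = 0.256 with an estimated correlation. Chemokines went both ways, with Cxcl10 down (-2.32 ± 0.21) and Cxcl1 up (1.20 ± 0.20). Of 16, 5 fell and 2 rose, or 3 up and 6 down adjusted over the list alone (adjusted p = 0.0199; adjusted p = 0.113 with an estimated correlation). Sterol genes rose in 7 of 18 cases and fell in 0, or 13 up and 0 down adjusted over the list alone (adjusted p = 2.86e-10). NRF2 targets rose in 9 of 15 cases and fell in 0, or 12 up and 0 down adjusted over the list alone (adjusted p = 4.57e-12). The heme-degrading enzyme Hmox1 was at 2.08 ± 0.63, adjusted p = 0.0619. The largest rises were those of the kinase Plk2 (3.16 ± 0.28), the endothelin receptor Ednrb (3.12 ± 0.17), the transporter Slc22a4 (3.10 ± 0.17), Gsta3 (2.89 ± 0.26) and, by at least 5.15-fold, Tent5c (adjusted p = 3.12e-06). A total of 830 genes passed, 417 up and 413 down. Without CpG replicate 1, CpG replicate 2 and HDL with CpG replicate 2 the count was 520, 522 and 542. On the chip with both groups the interferon median was -1.67, and with the chip in the model -1.68.

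The change that HDL made in the CpG response, tested as the difference of both CpG effects, passed for 101 genes, 67 up and 34 down. Genes whose CpG response was larger after HDL included Fpr2 (2.80 ± 0.20), Gpr84 (2.65 ± 0.19), H2-M2 (2.53 ± 0.29), Cdkn2b (2.27 ± 0.29) and Nfkbiz (2.19 ± 0.23). HDL alone had lowered Fpr2, Gpr84 and Nfkbiz, so they rose from a lower start. Genes with a smaller response included Gadd45a (-2.57 ± 0.24), Marveld1 (-2.37 ± 0.48), Ndrg1 (-2.22 ± 0.32), Fcgr2b (-1.85 ± 0.31) and Ccl12, which was not above background with HDL alone. Sterol genes, already higher with HDL alone, had a median of -0.79 (adjusted p = 4.26e-11). Of 18, 3 passed downwards and 0 upwards, or 0 up and 7 down adjusted over the list alone. NF-kB targets had a median of 0.55 (adjusted p = 5.36e-05), with 3 of 22 upwards and 0 downwards, or 5 up and 1 down adjusted over the list alone. Interferon-stimulated genes had a median of -0.31 (adjusted p = 0.0328; adjusted p = 0.716 with an estimated correlation). Of 30, 1 passed upwards and 2 downwards, or 2 up and 6 down adjusted over the list alone. Atf3 was at -0.04 and did not pass. Without any one of the 9 arrays of the HDL, CpG and HDL with CpG groups the count was 37 to 63, and with the chip in the model 263. On the single chip with all 4 groups the sterol median was -0.92.

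In the second experiment both ligands raised inflammatory genes in wild-type macrophages. CpG raised Socs3 (7.13 ± 0.38), the chemokines Cxcl1 (6.77 ± 0.27) and Cxcl2 (6.42 ± 0.28), Il1b (6.39 ± 0.26), Acod1 (6.36 ± 0.32), Tnf (5.21 ± 0.24), Ccl5 (4.93 ± 0.20), Cxcl10 (4.37 ± 0.27) and Il10 (4.13 ± 0.29). P3C raised Cxcl1 (6.90 ± 0.27), Socs3 (6.53 ± 0.38), Cxcl2 (6.51 ± 0.28), Acod1 (6.29 ± 0.32), Il1b (6.25 ± 0.26) and Tnf (5.51 ± 0.24). Il6 rose at least 8.75-fold with CpG and 6.42-fold with P3C, and the nitric oxide synthase Nos2 at least 1.89-fold with CpG (adjusted p = 2.39e-09, 3.16e-08 and 1.76e-05). Of 14 cytokines 13 rose with CpG and 12 with P3C and 0 fell, by either count (adjusted p = 8.08e-11 and 1.46e-10). All 23 NF-kB targets measured rose with each ligand by either count. Interferon-stimulated genes rose in 23 of 30 cases with CpG and 22 with P3C and fell in 0. Adjusted over the list alone, 25 and 23 rose and 0 fell. Their medians were 1.19 and 1.01 (adjusted p = 8.08e-11 and 6.8e-10). Cell cycle genes fell in 14 and 14 of 21 cases and rose in 0, or 15 and 15 down adjusted over the list alone. This list had an adjusted p = 0.000785 and 9.76e-05, and an adjusted p = 0.123 and 0.0871 with an estimated correlation. The largest falls with CpG were those of Fam214a (-4.59 ± 0.22), Cxcr4 (-4.38 ± 0.21), the signalling protein Rasgrp3 (-4.16 ± 0.27) and, by at least 13.9-fold and 12.2-fold, Hmga2-ps1 and the cannabinoid receptor Cnr2 (adjusted p = 3.62e-18 and 9.96e-17). With P3C, Cxcr4 fell (-4.50 ± 0.21), and Fam214a, Rasgrp3 and Cnr2 by at least 24.3-fold, 23.1-fold and 12.8-fold (adjusted p = 1.14e-17, 3.14e-15 and 3.15e-17). CpG changed 4703 of 9204 genes, 2037 up and 2666 down, and P3C 4589, 1984 up and 2605 down. On the chips with both groups the interferon medians were 1.43 and 0.68.

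HDL alone again raised sterol genes and lowered interferon-stimulated genes in wild-type cells, but here it also raised Cxcl1, Il1b, Tnf and Ccl5. The largest rises were those of Slc7a11 (4.09 ± 0.20), Cxcl1 (3.37 ± 0.27), the acetyl-CoA synthetase Acss2 (3.27 ± 0.18), Mvd (3.25 ± 0.17) and, by at least 11.7-fold, Chac1 (adjusted p = 2.94e-12). Il1b rose by 3.10 ± 0.26, Tnf by 1.12 ± 0.24 and Ccl5 by 0.69 ± 0.20. In the first experiment Tnf had fallen (-1.10 ± 0.26) and Il1b was at -0.65 ± 0.29, adjusted p = 0.22. Il10 fell (-0.99 ± 0.29) and Cxcl10 did not pass (-0.25 ± 0.27, adjusted p = 0.651). As a list the 14 cytokines did not pass, with 3 up and 1 down by either count (median 0.10, adjusted p = 0.0587). Nor did the 23 NF-kB targets, with 5 up and 2 down, or 5 up and 5 down adjusted over the list alone (median 0.03, adjusted p = 0.86). Sterol genes, among them Lss (3.14 ± 0.11) and Cyp51 (3.05 ± 0.23), rose in 15 of 18 cases and fell in 0, or 17 up and 0 down adjusted over the list alone. Their median was 1.87 (adjusted p = 1.36e-30). ATF4 targets rose in 11 of 18 cases and fell in 0, or 12 up and 0 down adjusted over the list alone (adjusted p = 8.82e-11). NRF2 targets rose in 8 of 15 and fell in 0, by either count (adjusted p = 8.96e-07). Interferon-stimulated genes, such as Ifi47 (-1.73 ± 0.29) and Ifit3 (-1.50 ± 0.16), fell in 16 of 30 cases and rose in 0, or 0 up and 18 down adjusted over the list alone. Their median was -0.68 (adjusted p = 8.82e-11). Cell cycle genes fell in 10 of 21 cases and rose in 0, by either count, with Mcm6 at -1.47 ± 0.26 (median -0.67, adjusted p = 1.12e-10). Cx3cr1 (-3.36 ± 0.23), Abcg1 (-3.05 ± 0.18), cyclin D1 (Ccnd1, -2.88 ± 0.18), Btbd11 (-2.48 ± 0.18) and Dmwd (-2.25 ± 0.24) fell most. In all, 1404 genes passed, 771 up and 633 down. On the single chip with both groups the interferon median was -0.34 and the sterol median 2.06, beside -0.65 and 1.88 with the chip in the model.

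HDL before either ligand lowered interferon-stimulated genes in wild-type cells of the second experiment as well. Against the ligand alone, 24 of 30 fell with CpG and 23 with P3C, 0 rose and 6 and 7 did not pass, or 26 and 25 down adjusted over the list alone. Their medians were -1.43 and -1.44 (adjusted p = 1.86e-21 and 1.74e-25). Ccl12 (-3.42 ± 0.31 with CpG, -3.28 ± 0.31 with P3C), Mx2 (-3.22 ± 0.18, -3.10 ± 0.18), Usp18 (-2.58 ± 0.17, -2.90 ± 0.17), Fcgr1 (-2.61 ± 0.20, -2.61 ± 0.20), Cxcl10 (-1.80 ± 0.27, -2.40 ± 0.27) and Il10 (-1.87 ± 0.29, -2.81 ± 0.29) fell in both. Ccnd1 (-2.66 ± 0.18) and Igsf9 (-2.65 ± 0.21) were among the 5 largest falls with CpG and Ch25h, a cholesterol-hydroxylating enzyme, with P3C (-2.78 ± 0.19). Il6 fell with P3C (-1.30 ± 0.39) and did not pass with CpG (-0.54 ± 0.39, adjusted p = 0.359), a contrast between ligands that was not tested. Tnf (0.31 ± 0.24, adjusted p = 0.394; -0.46 ± 0.24, adjusted p = 0.193), Il1b (-0.28 ± 0.26, adjusted p = 0.486; -0.50 ± 0.26, adjusted p = 0.185) and Ccl5 (-0.25 ± 0.20, adjusted p = 0.408; -0.45 ± 0.20, adjusted p = 0.129) did not pass with CpG or P3C. Of 14 cytokines, 8 fell with P3C and 1 rose, or 1 up and 9 down adjusted over the list alone. Their median was -0.55 (adjusted p = 2.62e-05). With CpG the cytokine median was -0.25 (adjusted p = 0.356), and 1 rose and 4 fell, by either count. Sterol genes rose in 17 and 17 of 18 cases and fell in 0, or 18 and 17 up adjusted over the list alone (medians 1.5 and 1.62). NRF2 targets rose in 12 and 13 of 15 and fell in 0, by either count. The largest rises in both were those of the lipoprotein receptor Lrp8 (3.07 ± 0.18 with CpG, 3.24 ± 0.18 with P3C) and of Acss2 (2.98 ± 0.18, 3.31 ± 0.18). The lipid droplet protein Plin2 (2.97 ± 0.27), Tent5c (2.73 ± 0.23) and Gsta3 (2.71 ± 0.20) followed with CpG, and Slc22a4 (3.24 ± 0.22), Ednrb (2.77 ± 0.19) and Chac1 (2.75 ± 0.26) with P3C. Hmox1 rose in both (1.89 ± 0.67, 2.57 ± 0.67), and Abcg1 was at least 3.44-fold and 4.25-fold lower (adjusted p = 5.75e-11 and 3.75e-12). HDL changed 1971 genes under CpG, 865 up and 1106 down, and 1714 under P3C, 882 up and 832 down. With only the groups compared in the model, 637 passed under CpG. Interferon medians within chips were -1.30 with CpG and -1.43 and -1.61 with P3C, beside -1.46 and -1.51 with the chip in the model.

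**Figure D2:**
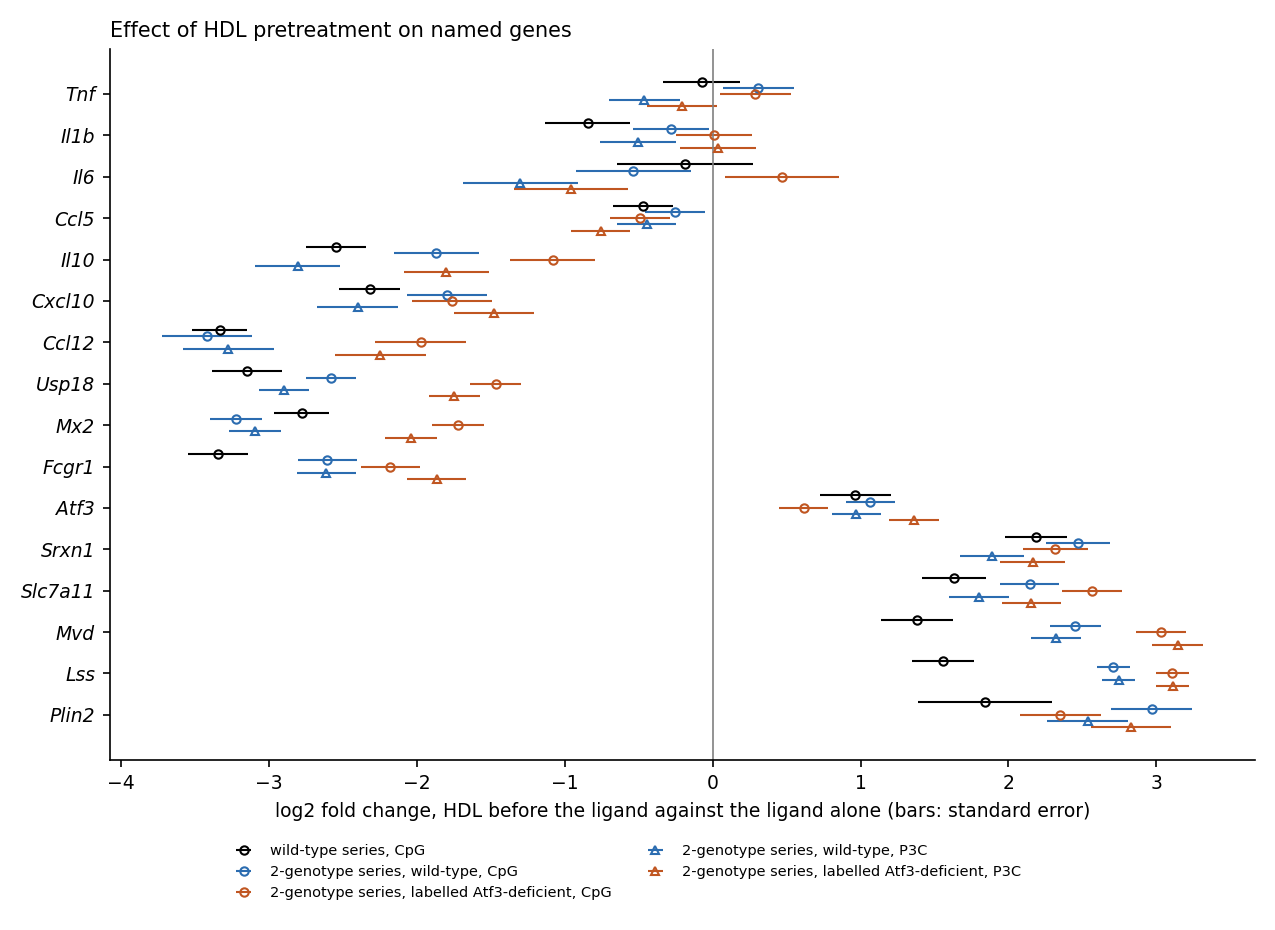
Log2 change of 16 genes between macrophages given HDL and a ligand and macrophages given the ligand alone, with CpG as circles and P3C as triangles, for the wild-type experiment (black) and for the wild-type (blue) and labelled Atf3-deficient (orange) cells of the second experiment. Points are log2 fold changes and bars SE over 3 arrays per group; Tnf lies between -0.46 and 0.31 in all 5 comparisons, while Ccl12, Usp18, Mx2 and Fcgr1 lie below 0 and Lss, Mvd and Plin2 above it.

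The wild-type comparisons of both macrophage experiments share no array. Across genes, which are not independent replicates, Pearson's r between the experiments was 0.873 for the CpG effect, 0.646 for HDL alone and 0.742 for HDL before CpG. Of 823 genes that passed for HDL before CpG in the first experiment and were tested in the second, 817 (99.3%) had the same sign there. In both experiments 346 rose and 326 fell, where 40.6 and 51.9 would by chance, and 0 passed in opposite directions under limma. For HDL alone 693 of 717 (96.7%) had the same sign. The cells of the experiments differed in sex-linked transcripts, with Xist detected on 0 of 12 arrays of the first and 36 of 36 of the second.

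Unstimulated macrophages labelled Atf3-deficient expressed interferon-stimulated genes far above wild-type cells. All 30 measured were higher, by either count, with a median of 2.28 (adjusted p = 8.81e-62). Among them were Oasl1 (3.75 ± 0.21), Isg15 (3.73 ± 0.33), Ifit2 (3.50 ± 0.19) and the interferon regulator Irf7 (3.46 ± 0.16). The other large rises were those of Slfn1 (at least 13.5-fold, adjusted p = 4.82e-14), Ifi213 (3.82 ± 0.20) and Ch25h (3.75 ± 0.19). Ccl12 (3.06 ± 0.31), Cxcl10 (2.24 ± 0.27), Ccl5 (1.13 ± 0.20), Il10 (1.32 ± 0.29), Tnf (0.85 ± 0.24) and the stress gene Ddit3 (1.12 ± 0.25) were higher too. Of 16 chemokines 8 rose and 1 fell, by either count (adjusted p = 7.78e-05, adjusted p = 0.0517 with an estimated correlation). Cell cycle genes were lower in 13 of 21 cases and higher in 0, or 1 up and 13 down adjusted over the list alone, with Cdc20 at -1.22 ± 0.17 and Top2a at -1.21 ± 0.26. That list had an adjusted p = 5.95e-07 and an adjusted p = 0.0507 with an estimated correlation. Of 5 fibroblast markers 4 were higher and 0 lower, by either count, with Dcn at 2.33 ± 0.31 and Col1a1 at 1.54 ± 0.25 (median 1.33, adjusted p = 7.48e-05). The largest falls were those of Erdr1 (at least 73.5-fold, adjusted p = 4.12e-21), Pisd-ps3 (-4.18 ± 0.33), the growth factor Gdf3 (-3.67 ± 0.34), Col18a1 (-3.60 ± 0.16) and caveolin Cav1 (-3.39 ± 0.24). In all, 1222 genes differed, 595 higher and 627 lower. Within the 2 chips that held both groups the interferon medians were 2.23 and 2.07, and with the chip in the model 2.33.

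**Figure D3:**
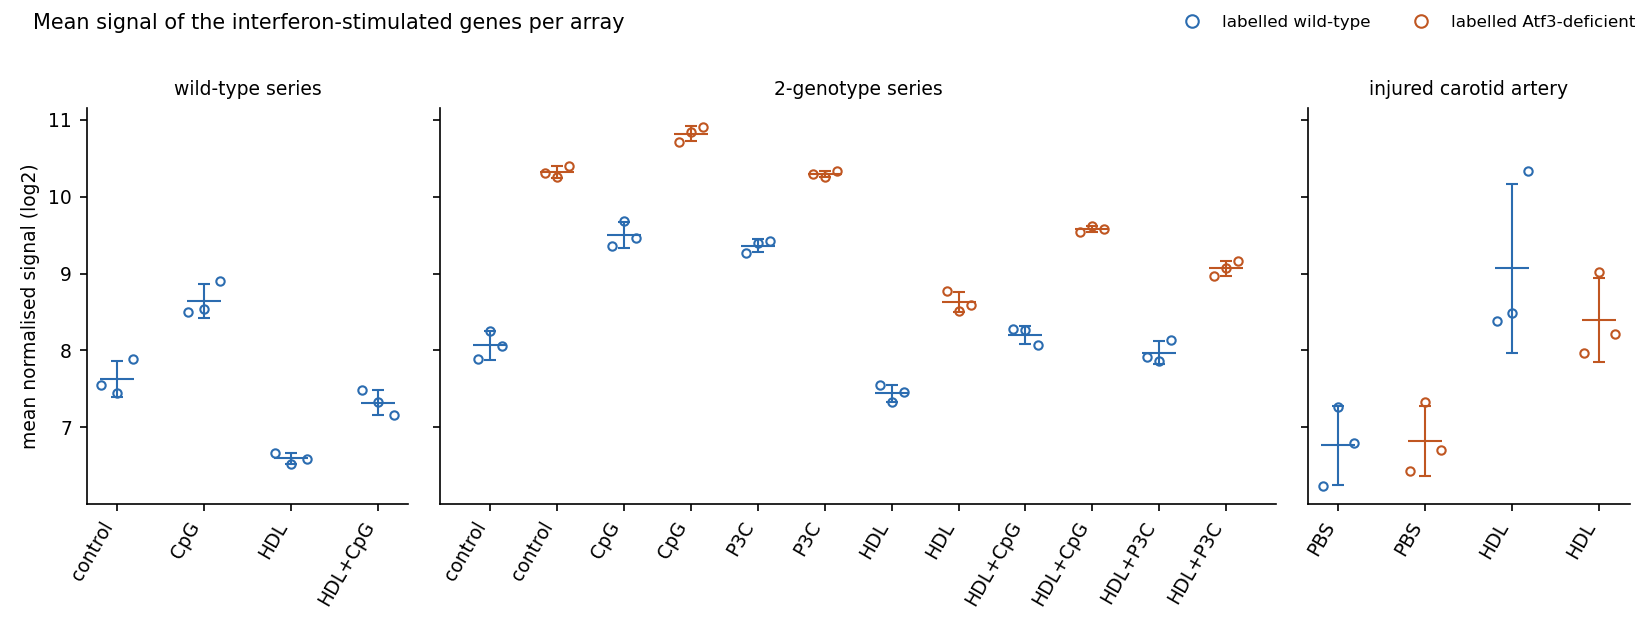
Mean log2 signal of the interferon-stimulated genes on each array (open circles) with the group mean (dash) and SD (bar), 3 arrays per group, for both macrophage experiments and the injured artery. The list was higher in unstimulated cells labelled Atf3-deficient than in wild-type cells by a median of 2.28, and each macrophage HDL group lies below the group of the same label and ligand without HDL.

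The response of interferon-stimulated genes to both ligands differed between the labels. In cells labelled Atf3-deficient, CpG and P3C raised Socs3 (7.0 ± 0.38 and 6.86 ± 0.38), Il1b (6.01 ± 0.26 and 5.94 ± 0.26) and Tnf (4.45 ± 0.24 and 4.48 ± 0.24). CpG raised Saa3 (5.97 ± 0.37) and, at least 63.7-fold and 51.7-fold, Lcn2 and Edn1 (adjusted p = 5.96e-20 and 2.45e-20), and P3C raised Cxcl1 (6.58 ± 0.27) and Cxcl2 (6.44 ± 0.28). All 23 NF-kB targets rose with each ligand by either count. CpG changed 4758 genes in these cells, 1900 up and 2858 down, and P3C 4563, 1977 up and 2586 down. Interferon-stimulated genes had medians of 0.27 and -0.22 here. Tested as the difference between labels, the CpG response of the list differed by a median of -0.88 (adjusted p = 2.56e-18). Of 30, 14 passed downwards and 0 upwards, or 0 up and 20 down adjusted over the list alone. The P3C response differed by a median of -1.07 (adjusted p = 5.3e-45), with 16 downwards and 0 upwards, or 0 up and 25 down adjusted over the list alone. Mx2 differed by -2.45 ± 0.25 and -2.89 ± 0.25, Rnf213 by -2.64 ± 0.42 and -2.51 ± 0.42, and Cmpk2 by -2.14 ± 0.34 and -2.67 ± 0.34. Sterol genes had a lower response, with medians of -0.74 and -0.75 (adjusted p = 1.82e-05 and 6.75e-11). Of 18, 6 and 7 passed downwards and 0 upwards, or 10 and 8 down adjusted over the list alone. AP-1 and immediate early genes, which include Atf3, had a higher response, with medians of 0.51 and 0.19 (adjusted p = 8.15e-05 and 0.0127). Of 16, 3 and 3 passed upwards and 0 and 1 downwards, or 4 up and 0 down, and 6 up and 2 down, adjusted over the list alone. Egr2 (1.51 ± 0.25) and Fosl2 (1.40 ± 0.19) were among them with CpG. Gab1 had a larger response to each ligand (1.92 ± 0.20 and 2.17 ± 0.20). Tnf did not differ past the test in its response to CpG (-0.76 ± 0.34, adjusted p = 0.251) or P3C (-1.03 ± 0.34, adjusted p = 0.126). The CpG response differed for 287 genes, 88 higher and 199 lower, and the P3C response for 202, 76 higher and 126 lower. The first count was 175 to 190 without wild-type control replicate 2 or 3, labelled Atf3-deficient control replicate 3 or CpG replicate 1, and 474 without wild-type CpG replicate 2. With median scaling it was 182, and with only the groups compared in the model 69. No chip held all 4 groups of either difference, and with the chip in the model 183 and 118 genes passed.

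HDL alone lowered all 30 interferon-stimulated genes measured in cells labelled Atf3-deficient, by either count, among them Cmpk2 (-3.02 ± 0.24) and Isg15 (-2.89 ± 0.33). Their median was -1.67 (adjusted p = 5.41e-34). Sterol genes rose in 15 of 18 cases and fell in 0, by either count (median 1.41, adjusted p = 5.62e-19). The largest rises were those of Slc7a11 (3.95 ± 0.20), Ednrb (3.35 ± 0.19), Chac1 (3.09 ± 0.26), Hsd17b7, a cholesterol synthesis enzyme (2.98 ± 0.18), and Arg2 (at least 6.77-fold, adjusted p = 1.71e-11). Abcg1 (-3.97 ± 0.18), Ccnd1 (-3.52 ± 0.18), Cx3cr1 (-3.46 ± 0.23), Cmpk2 and Il10 (-2.95 ± 0.29) fell most. Tnf fell (-1.11 ± 0.24) where it had risen in wild-type cells of the same experiment, and this difference passed (-2.23 ± 0.34). In wild-type cells of the first experiment, however, HDL alone had lowered Tnf as well. Differences downwards also passed for Acod1 (-2.42 ± 0.45), Cd69 (-2.41 ± 0.37), Cd40 (-2.23 ± 0.28), Mmp13 (-2.12 ± 0.29), Cxcl1 (-2.0 ± 0.38), Il10 (-1.96 ± 0.41) and Cxcl10 (-1.84 ± 0.38). Gab1 (1.81 ± 0.20), Gpr34 (1.29 ± 0.24) and Il7r (1.27 ± 0.29) differed upwards. For interferon-stimulated genes the difference in the HDL effect, over the same control arrays, had a median of -1.09 (adjusted p = 1.13e-38). Of 30, 14 passed downwards and 0 upwards, or 0 up and 20 down adjusted over the list alone. For chemokines the median was -0.43 (adjusted p = 1.62e-08), with 6 of 16 downwards and 0 upwards, or 1 up and 6 down adjusted over the list alone. HDL changed 2138 genes in these cells, 1229 up and 909 down, and the difference passed for 118, 28 higher and 90 lower. With median scaling it passed for 78 genes, 10.3% of them upwards in place of 23.7%. That difference passed for 66 and 76 genes without control replicate 3 and HDL replicate 2 of the cells labelled Atf3-deficient. No chip held the groups of either comparison.

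HDL with a ligand was also compared with the ligand alone in cells labelled Atf3-deficient. This comparison includes the effect of HDL alone, and a change of the ligand response by HDL was not tested here. With HDL, interferon-stimulated genes fell in 25 of 30 cases under each ligand and rose in 0, or 0 up and 27 down adjusted over the list alone. Their medians were -1.35 and -1.12 (adjusted p = 2.09e-24 and 9.59e-24). Sterol genes rose in 17 and 15 of 18 cases and fell in 0, by either count (medians 1.98 and 1.98). Cxcl10 (-1.76 ± 0.27 with CpG, -1.48 ± 0.27 with P3C), Il10 (-1.08 ± 0.29, -1.80 ± 0.29), Ccl12 (-1.97 ± 0.31, -2.25 ± 0.31) and Fcgr1 (-2.18 ± 0.20, -1.87 ± 0.20) fell, as did Isg15 (-1.98 ± 0.33) with CpG and Mx2 (-2.04 ± 0.18) with P3C. Ccnd1 (-2.49 ± 0.18, -2.43 ± 0.18) and Abcg1 (at least 3.62-fold and 3.99-fold lower, adjusted p = 5.88e-13 and 3.34e-13) were among the largest falls in both. Nox1 (-2.33 ± 0.28) and Adora3 (-2.17 ± 0.24) were among them under CpG and Ch25h (-2.30 ± 0.19) and Btbd11 (-2.16 ± 0.18) under P3C. Lss (3.11 ± 0.11, 3.11 ± 0.11), Mvd (3.03 ± 0.17, 3.14 ± 0.17) and Hsd17b7 (2.97 ± 0.18, 2.99 ± 0.18) were among the largest rises in both, with Plk2 (2.96 ± 0.23) and Stard4 (2.85 ± 0.27) under CpG and Cyp51 (2.98 ± 0.23) and Lrp8 (2.97 ± 0.18) under P3C. Tnf (0.29 ± 0.24, adjusted p = 0.459; -0.21 ± 0.24, adjusted p = 0.624), Il1b (0.01 ± 0.26, adjusted p = 0.991; 0.04 ± 0.26, adjusted p = 0.949) and Il6 (0.47 ± 0.39, adjusted p = 0.462; -0.96 ± 0.39, adjusted p = 0.0848) did not pass with either ligand. Osm (2.05 ± 0.17), Il1a (1.46 ± 0.23), Cxcl1 (1.73 ± 0.27) and Ptgs2 (1.28 ± 0.43) rose under CpG. In all, 1802 genes passed under CpG, 991 up and 811 down, and 1704 under P3C, 848 up and 856 down. Pearson's r across genes between the labels was 0.725 under CpG and 0.766 under P3C. Interferon medians within chips were -1.28 with CpG and -1.09 and -1.10 with P3C, beside -1.31 and -1.11 with the chip in the model. With only the groups compared in the model, 1000 genes passed under CpG.

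The difference between labels in the HDL effect was tested directly and passed for few genes. Under CpG 46 differed, 36 upwards and 10 downwards. Hsd17b7 (1.52 ± 0.26), the matrix protease Mmp9 (1.52 ± 0.27), Mx2 (1.5 ± 0.25), Agpat5 (1.42 ± 0.27), Narf (1.38 ± 0.22) and Il1a (1.35 ± 0.32) had a higher HDL effect in cells labelled Atf3-deficient, and Ifi204 (-2.13 ± 0.50) and Dapk1 (-1.32 ± 0.31) a lower one. Under P3C 38 differed, 26 upwards and 12 downwards (68.4% upwards), but 13 with median scaling, 46.2% of them upwards, and 18 with only the groups compared in the model. Zfp36l1 (1.48 ± 0.21), Il1a (1.38 ± 0.32), Sqle (1.28 ± 0.20), Nr1h3, which encodes LXR alpha (1.27 ± 0.23), Msmo1 (1.20 ± 0.18) and Usp18 (1.15 ± 0.24) had a higher effect and Wdr45 (-1.11 ± 0.23) a lower one. Csf2, Ifnb1, Rabgap1l, Layn, Flrt2, Prss46 and Apol9b are given no value because their signal in some of the groups was not above background. The difference did not pass for Atf3 (-0.45 ± 0.24, adjusted p = 0.474 with CpG; 0.39 ± 0.24, adjusted p = 0.789 with P3C), Tnf (-0.02 ± 0.34, adjusted p = 0.99; 0.25 ± 0.34, adjusted p = 0.946) or Il6 (1.0 ± 0.55, adjusted p = 0.493; 0.34 ± 0.55, adjusted p = 0.95). Nor did it pass for Il1b (0.29 ± 0.36, adjusted p = 0.81; 0.54 ± 0.36, adjusted p = 0.838), Il10 (0.79 ± 0.41, adjusted p = 0.462; 1.0 ± 0.41, adjusted p = 0.517) or Cxcl10 (0.04 ± 0.38, adjusted p = 0.981; 0.92 ± 0.38, adjusted p = 0.54). The HDL effect on cytokines was higher in cells labelled Atf3-deficient under P3C, with a median of 0.43 (adjusted p = 1.07e-06). Of 14, 3 passed upwards and 0 downwards, or 3 up and 1 down adjusted over the list alone. Under CpG the cytokine median was 0.48, with 2 upwards and 0 downwards, or 4 up and 0 down adjusted over the list alone (adjusted p = 0.0036; adjusted p = 0.222 with an estimated correlation). Sterol genes had a higher HDL effect in these cells, with medians of 0.41 and 0.33 (adjusted p = 0.00473 and 1.97e-09; adjusted p = 0.222 under CpG with an estimated correlation). Of 18, 2 and 3 passed upwards and 0 downwards, or 4 and 6 up adjusted over the list alone. On simulated data with the spread of these arrays but no chip effects, 61 of 100 genes with a log2 difference of 1 were recovered for the CpG comparison. The count under CpG was 20 with median scaling, 5 with the chip in the model and 0 under limma with only the 4 groups in it, where 557 genes had an unadjusted p under 0.05. It was 22 to 29 without wild-type HDL with CpG replicate 3, labelled Atf3-deficient CpG replicate 3 or any array of HDL with CpG of that label, and 74 without CpG replicate 2 of either label. Under P3C it was 17 to 25 without any wild-type P3C array, wild-type HDL with P3C replicate 2 or 3, or, of the other label, P3C replicate 1 or 3 or HDL with P3C replicate 1 or 2. On the single chip with the 4 CpG groups the cytokine median was 0.48, and no chip held the 4 P3C groups.

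CpG-induced genes were then followed as a set, chosen in an experiment with other arrays than those tested. The 543 genes that CpG raised at least 2-fold in the first experiment had a median HDL effect under CpG of -0.06 in wild-type cells of the second, with 297 (54.7%) lower, 81 rising and 115 falling (adjusted p = 0.52). In cells labelled Atf3-deficient it was -0.09, with 314 (57.8%) lower (adjusted p = 0.208), and the difference was 0.01 (adjusted p = 0.832). Without wild-type CpG replicate 1 the wild-type median of -0.14 and the difference of 0.08 passed. Under P3C the set was lower with HDL in wild-type cells, with a median of -0.21, 359 (66.1%) lower, 54 rising and 141 falling (adjusted p = 0.000153). In cells labelled Atf3-deficient the median was -0.10 (adjusted p = 0.147). The difference was 0.12 (adjusted p = 0.000111), with 7 genes passing upwards and 0 downwards under limma. The 755 genes that CpG raised at least 2-fold in wild-type cells of the second experiment had a median HDL effect of -0.15 in the first, with 453 of 744 (60.9%) lower (adjusted p = 0.00438). Without CpG replicate 3 this result did not pass. With an estimated correlation these 3 calls were lost, with unadjusted camera p of 0.0843, 0.0753 and 0.165. The 10 interferon-stimulated members of the first set had medians of -1.78 and -2.30 in wild-type cells under CpG and P3C, and the other members -0.05 and -0.20.

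In injured arteries of wild-type mice HDL went with higher interferon and inflammatory gene signals, none of which passed over all genes. Interferon-stimulated genes had a median of 2.37 (adjusted p = 7.3e-21; adjusted p = 0.237 with an estimated correlation). Of 29, 0 passed over all genes under limma and 24 passed upwards adjusted over the list alone. Oasl1 was at 3.93 ± 0.72, Cmpk2 at 3.51 ± 0.70, Ifit3 at 3.27 ± 0.95, Irf7 at 3.19 ± 0.81 and Cxcl10 at 4.95 ± 1.06. Tnf was at 2.83 ± 0.75, Il1a at 2.17 ± 0.53 and Il15 at 1.76 ± 0.36, these 8 with an adjusted p = 0.192, and Il6 at 0.05 ± 0.52, adjusted p = 0.95. The smallest p belonged to Il18 (2.08 ± 0.37), the TNF receptor adaptor Traf1 (1.67 ± 0.30) and Oasl1. Cytokines had a median of 1.45, with 5 of 10 up adjusted over the list alone (adjusted p = 5e-05; adjusted p = 0.157 with an estimated correlation). NF-kB targets had a median of 0.89, with 13 of 21 up adjusted over the list alone (adjusted p = 1.25e-08; adjusted p = 0.237 with an estimated correlation). Markers of cell types moved with them. Medians were 1.57 for macrophage and monocyte markers, 1.81 for T and B lymphocyte markers and 1.36 for erythrocyte and platelet markers (adjusted p = 2.73e-06, 0.00131 and 0.0111). Contractile smooth muscle, fibroblast and endothelial markers had medians of -2.16, -1.88 and -1.72 (adjusted p = 0.000727, 0.000153 and 0.0099). With an estimated correlation none of these 6 marker lists passed, with adjusted p from 0.456 to 0.573. Fcgr1 was at 2.27 ± 0.74, Aif1 at 2.24 ± 0.73, Myh11 at -3.16 ± 1.21, Lum at -3.48 ± 1.30 and Cldn5 at -3.01 ± 1.12. No gene of 9353 passed under limma and 2154 had an unadjusted p under 0.05, while 4309 passed with the deposited matrix values, 1 up and 4308 down. HDL replicates 1 and 3 had few detected probes, 9266 and 11094. Without them, a choice made after the data were seen, the interferon median was 1.71 and the smooth muscle median 0.07, and without HDL replicate 2, 2357 genes passed. Interferon medians within the chips were 2.23 and 2.39, and macrophage medians 2.50 and 0.97. Those matrix values, which carry no scaling between arrays, gave an interferon median of 0.57, an NF-kB median of -0.34 and an erythrocyte and platelet median of -0.01 where the median of all genes was -0.63.

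**Figure D4:**
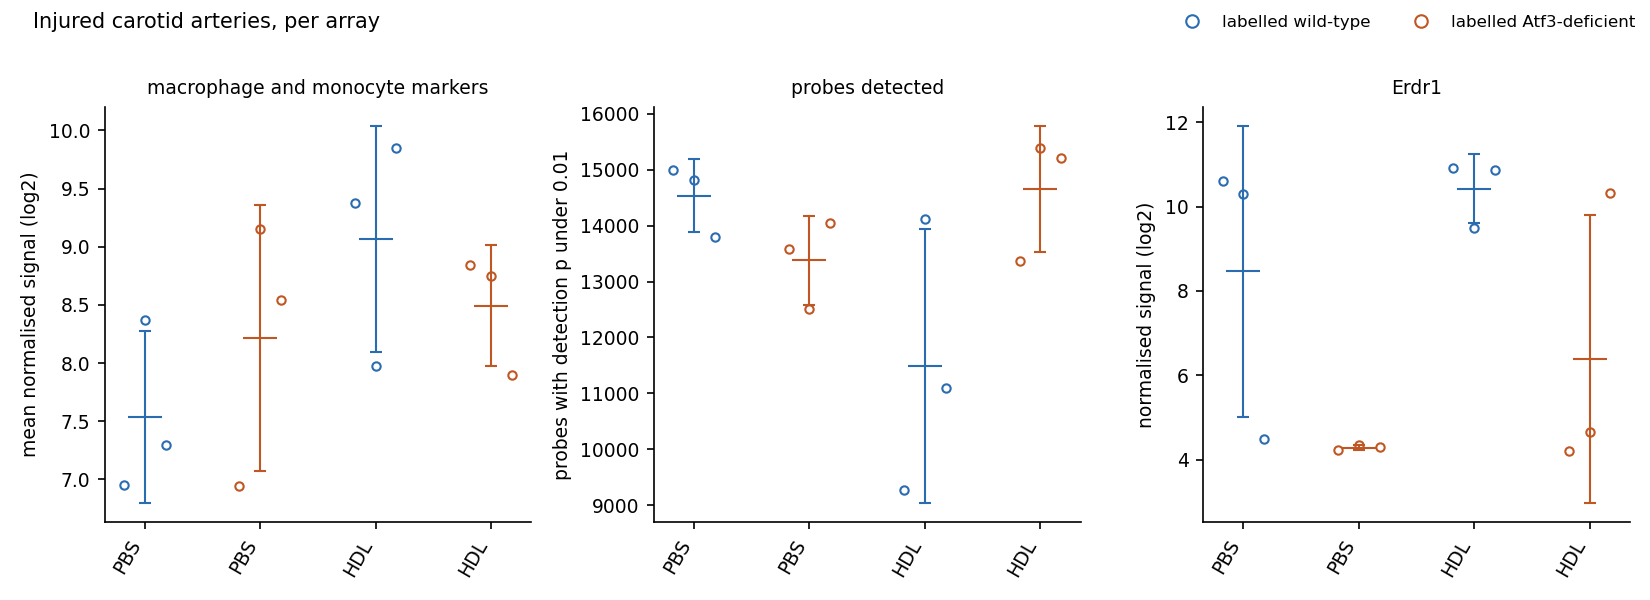
Each injured artery array by its mean log2 signal of macrophage and monocyte markers, its number of detected probes and its log2 Erdr1 signal, with 3 arrays per group. The wild-type HDL group holds the array with the fewest detected probes, 9266, and 1 wild-type PBS array (Erdr1 at 4.48) and 1 HDL array labelled Atf3-deficient (10.33) lie at the Erdr1 level of the other label.

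Arteries labelled Atf3-deficient also had higher interferon signals with HDL, with a median of 1.44 (adjusted p = 1.39e-35; adjusted p = 0.283 with an estimated correlation). Of 29 genes 0 passed over all genes under limma and 14 passed upwards adjusted over the list alone. Isg15 was at 2.57 ± 0.59, Ifit3 at 2.91 ± 0.95, Cmpk2 at 2.56 ± 0.70, Irf7 at 2.55 ± 0.81 and Cxcl10 at 2.77 ± 1.06, each with an adjusted p of 1. Pisd-ps3 (1.63 ± 0.35) and leptin, Lep (-2.09 ± 0.52), had the smallest p with Isg15 and the same adjusted p. Macrophage and monocyte markers had a median of 0.19 (adjusted p = 0.155). Adipocyte and skeletal muscle markers, of tissue around an artery, had medians of -1.93 and -1.45 (adjusted p = 0.000488 and 0.00608; adjusted p = 0.484 and 0.507 with an estimated correlation). Without PBS replicate 1 the macrophage median was -0.32, and without PBS replicate 2 the skeletal muscle median was 0.48. Interferon medians within the chips were 1.66 and 1.41, while that of NF-kB targets, 0.27 on all arrays, was 0.42 and -0.23. The difference between labels in the HDL effect had a median of -0.77 for interferon-stimulated genes (adjusted p = 0.00015; adjusted p = 0.569 with an estimated correlation). It was -1.29 for macrophage markers and 2.33 for smooth muscle markers (adjusted p = 9.94e-05 and 0.000286; adjusted p = 0.569 and 0.569 with an estimated correlation). Without the low-signal arrays these 3 medians were -0.09, -0.21 and 0.16 and none passed (adjusted p = 0.692, 0.692 and 0.939). With the deposited matrix values they were 0.69, 0.40 and 2.36, where the median of all genes was 0.91, and the smooth muscle list did not pass (adjusted p = 0.736). Cxcl10 was at -2.18 ± 1.5, adjusted p = 0.757 and Tnf at -1.35 ± 1.06, adjusted p = 0.764, and the smallest p belonged to Elf3, Casp12 (1.14 ± 0.29) and Dnajb4 (1.77 ± 0.46). With PBS the labels differed by a median of 0.08 in interferon-stimulated genes and 2.31 in skeletal muscle markers (adjusted p = 0.654 and 2.39e-05; adjusted p = 0.587 for the latter with an estimated correlation). Macrophage markers were already higher there by a median of 0.76 and smooth muscle markers lower, at -0.84 (adjusted p = 0.000197 and 0.00763; adjusted p = 0.597 and 0.653 with an estimated correlation). Tmco6 (-0.79 ± 0.25), Rnu6 (2.24 ± 0.72) and Gng2 (1.06 ± 0.36) had the smallest p there. No gene passed in these 3 comparisons under limma, and 129, 390 and 57 genes had an unadjusted p under 0.05 for HDL, for the difference and for PBS. On simulated data 4 of 100 genes with a log2 difference of 1 and 38 of 100 with 2 were recovered for the difference. Without the 2 arrays whose Erdr1 signal was that of the other label, a choice made after the data were seen, 4 genes passed between the labels with PBS. Without wild-type HDL replicate 2, 431 passed for the difference, and without PBS replicate 3, 1 passed for HDL in arteries labelled Atf3-deficient. The set of CpG-induced genes had median HDL effects of 0.36 in wild-type arteries and 0.14 in those labelled Atf3-deficient and a difference of -0.25 (adjusted p = 3.73e-08, 5.58e-05 and 0.000111). With an estimated correlation the unadjusted p were 0.0337, 0.093 and 0.111. The set difference did not pass without the low-signal arrays (-0.09), without the arrays with the Erdr1 signal of the other label (-0.05), with median scaling (-0.52) or without the detection filter (-0.21).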

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

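Tests chosen only after the result was seen were those of low-signal artery arrays, of the chips in the artery, of macrophages in wild-type arteries, and, for the set under P3C, of single arrays and of the starting level of interferon-stimulated genes.

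The responses that differed between the labels were taken up because the difference itself passed a test. These were the CpG response (287 genes), the P3C response (202), the effect of HDL alone (118) and the effects of HDL under CpG (46) and under P3C (38). Among lists they were interferon-stimulated genes in the CpG response (-0.88), the P3C response (-1.07) and the HDL effect (-1.09), sterol genes in the CpG response (-0.74), the P3C response (-0.75) and the HDL effect under P3C (0.33), AP-1 and immediate early genes in the CpG response (0.51) and the P3C response (0.19), chemokines in the HDL effect (-0.43) and cytokines in the HDL effect under P3C (0.43), all as medians on the log2 scale. Differences in the ligand responses and HDL alone share control arrays and are not independent. The set of CpG-induced genes differed in the HDL effect under P3C (0.12) and in the artery (-0.25). Both calls were lost with an estimated correlation (unadjusted camera p of 0.0753 and 0.111). Probes with no gene listed also responded to CpG, 415 of 2192 in the first experiment (193 up, 222 down) and 888 of 2244 in wild-type cells of the second (388 up, 500 down).

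Interferon-stimulated genes were higher in unstimulated macrophages labelled Atf3-deficient, all 30 of them. Chips do not account for it, since the median was 2.07 within the chip where it was lower. Nor does background correction or normalisation, since the lowest median over these settings was 1.62, or a single array, since the lowest median with 1 array left out was 2.19. The pattern was found and tested on the same arrays. Whether it comes from Atf3 or from another difference between the animals or cultures stays open and untested.

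The same list had higher medians in arteries of HDL-injected mice, but 0 of 29 genes passed under limma in either label (2154 and 129 of all genes at an unadjusted p under 0.05), and both list calls were lost with an estimated correlation (adjusted p = 0.237 and 0.283). The chip does not account for the medians, since the chips hold HDL and PBS arrays alike and the lowest median within a chip was 1.41, nor do low-signal arrays in arteries labelled Atf3-deficient, none of which was of low signal and where the median was 1.44. In wild-type arteries low-signal arrays stay open, since leaving them out (1.711) leaves 1 HDL array. More macrophages in the tissue pieces are a candidate there, with a marker median of 1.57, although no marker passed over all genes. That median includes the low-signal arrays, and without them the difference between labels in the markers was smaller. In arteries labelled Atf3-deficient the markers had a median of 0.19, under the bound of 0.5 set for them. The difference of array means, 0.28 ± 0.725 (SE, n = 3), is too imprecise there to exclude more macrophages. A difference in tissue content and a response to HDL therefore cannot be told apart in these arrays.

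The set of CpG-induced genes was lowered less by HDL under P3C in cells labelled Atf3-deficient. The call was lost with an estimated correlation (unadjusted camera p of 0.0753), and the pattern was first written for CpG, where the difference was 0.01 (adjusted p = 0.832), and moved to P3C after the set results were seen. A single array does not account for it, since the lowest difference with 1 array left out was 0.10. A different starting level of interferon-stimulated genes stays open: the difference was 0.12 (0.1165) without the 10 of them among 543 members, too few to move the median under 0.1141 whichever were left out. Other splits of the arrays gave differences as large, so chance stays open as well.

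Other splits of the arrays were counted for each comparison. The 10 splits of 3 against 3 arrays are too few for a share under 0.05, and for counts of genes the real value and the highest other were 3052 and 0 for CpG, 722 and 6 for HDL and 830 and 2 for HDL before CpG in the first experiment. For wild-type cells of the second they were 4703 and 648 for CpG, 4589 and 0 for P3C, 1404 and 0 for HDL, 1971 and 84 for HDL before CpG and 1714 and 0 for HDL before P3C; for cells labelled Atf3-deficient 4758 and 0, 4563 and 0, 2138 and 0, 1802 and 4, and 1704 and 1 in the same order; and 1222 and 0 between the labels in control cells. Arteries gave 0 and 195 for HDL in wild-type (195 with wild-type HDL replicates 1 and 3 and PBS replicate 3 against the rest), 0 and 0 for HDL in the other label, and 0 and 7 between the labels. For the set medians they were -0.15 and 0.15 in the first experiment, -0.06 and 0.14 for CpG and -0.21 and 0.10 for P3C in wild-type cells, -0.09 and 0.07, and -0.10 and 0.05, in cells labelled Atf3-deficient, and 0.36 and 0.26, and 0.14 and 0.24, in arteries of wild-type and of the other label. As many splits as 1 (the real one), 2 (the set in the first experiment), 5 (the set under CpG in wild-type cells), 3 (the set in arteries labelled Atf3-deficient) or 10 (the artery counts of 0) gave a result as large.

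For differences of differences 100 of the possible splits were drawn. For the artery the real count is 0, so that all 100 are as large by definition and say nothing (highest other 1028). For the others chance could not be excluded by this count, which includes splits that hold part of the real effects. For the change of the CpG response by HDL 6, the real one included, gave as many genes (real 101, highest other 1572); the split with 1572 measures the sum of both effects, and without it 5 did (highest other 1367). Between the labels the numbers were 12 for the CpG response (287, 1754), 9 for the P3C response (202, 744), 15 for HDL alone (118, 917), 21 for HDL under CpG (46, 1461) and 18 under P3C (38, 814). For the set, 94 were as large under CpG (0.01, 0.33), 30 under P3C (0.12, 0.26) and 13 in the artery (-0.25, 0.41). The macrophage splits with the highest counts call several times the real number, which points to a structure of the samples: they exchange more arrays in one pair of groups than in the other. In the first experiment arrays with HDL were exchanged with arrays without it, so such splits hold part of the HDL effect itself. Between the labels arrays of the same treatment were exchanged, so such splits hold part of the difference between the labels itself.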

How the results depend on the processing

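Array quality weights and the settings without low-signal arrays or without arrays of the other label's Erdr1 were chosen after the data were seen; limma stopped before the weights converged in all 3 experiments, so those values are given for completeness. Of 386 counts under an alternative 316 lay within 1.5 times the reported count and 70 did not. Of 39114 values of named genes 37386 passed in the same direction or were short of the threshold in both settings, 624 came to pass it, 1104 no longer passed and 0 reversed. Of 9390 list results 8781 stayed, 177 came to pass, 417 no longer passed and 15 reversed. Of 174 set results 157 stayed, 3 came to pass, 12 no longer passed and 2 reversed in test direction only. These were for the difference in HDL under CpG, with a positive median throughout. Results short of the threshold in both settings were not counted as reversed, although 826 gene values and 507 list results of this kind changed sign. Signal over background limits the wild-type HDL arteries, where 2 arrays had few detected probes (9266 and 11094). Quantile normalisation and median scaling placed the median gene differently, at -0.11 and 0.01 for CpG in the first experiment, -0.11 and 0.20 for HDL in wild-type arteries and 0.04 and -0.27 for the artery difference; the deposited matrix values placed it at -0.63 and 0.91 in the last 2. Except where the construction shows it, the cause was not tested.

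With an estimated correlation 6 set results no longer passed, at -0.1484 (HDL before CpG, first experiment), -0.2113 and 0.1204 (HDL under P3C, wild-type and difference) and 0.3562, 0.1392 and -0.2491 (artery wild-type, labelled Atf3-deficient and difference). Both without normexp and with the deposited matrix values, 152 genes passed for the change of the CpG response by HDL and 82 for the difference in HDL under CpG. Median scaling gave 182 for the difference in the CpG response, 78 in HDL alone, 20 in HDL under CpG and 13 in HDL under P3C, and -0.5173 for the artery set difference, which no longer passed. Of those that passed, the share upwards went from 23.7% to 10.3% (HDL alone) and from 68.4% to 46.2% (HDL under P3C) with median scaling, from 66.3% to 79.0% for the change of the CpG response, and from 78.3% to 68.3% for HDL under CpG without normexp. With the deposited matrix values 4309 genes passed for HDL in wild-type arteries. The list test, which compares t-statistics, turned for adipocyte markers there (median -0.9118, adjusted p = 0.0124) and for fibroblast, smooth muscle and endothelial markers in the artery difference (adjusted p = 0.736, 0.736 and 0.0857). Their medians of 2.243, 2.364 and 1.734 stayed above the median of all genes.

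Without the detection filter the set under P3C in cells labelled Atf3-deficient passed (-0.101) and the artery difference did not (-0.2087). With the chip in the model 263 genes passed for the change of the CpG response, 183 and 118 for the differences in the CpG and P3C responses and 5 for HDL under CpG; as a random effect it gave 261 for the first. With only the groups compared in the model, which leaves fewer degrees of freedom, 333 passed for HDL in the first experiment, 637 and 1000 for HDL before CpG in wild-type and labelled Atf3-deficient cells, 69 for the difference in the CpG response, 0 for HDL under CpG and 18 under P3C. Array weights gave 4755, 2317 and 4481 for CpG, HDL and HDL before CpG in the first experiment and 467 for the change. They gave 3603 for HDL in cells labelled Atf3-deficient, 2803 between the labels and 594, 297 and 88 for the differences in P3C, HDL alone and HDL under P3C. For HDL in arteries labelled Atf3-deficient they gave 830, with lymphocyte markers at -0.08206 (reversed). The set was at -0.1803 in the first experiment (no longer passing), -0.1241 under CpG in wild-type cells (passing) and 0.07161 for the difference (passing).

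Without low-signal arrays, smooth muscle markers reversed to 0.06975 in wild-type arteries, and in the artery difference antigen presentation (0.2711), lysosome (0.305), smooth muscle (0.1601) and erythrocyte (0.05969) lists reversed and the set no longer passed (-0.08805). Without the arrays of the other label's Erdr1 4 genes passed between the labels with PBS and the artery set difference did not pass (-0.05309).

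Leaving out each array in turn gave 395 to 962 genes for HDL, 520 to 810 for HDL before CpG and 37 to 105 for the change in the first experiment, and -0.1831 to -0.1334 for its set. The differences between labels ran from 175 to 474 for CpG, 66 to 118 for HDL alone, 22 to 74 for HDL under CpG and 17 to 32 under P3C, with sets from -0.1439 to -0.02179 for HDL under CpG in wild-type cells and from -0.02521 to 0.07738 for the difference. In arteries they ran from 0 to 2357 for HDL in wild-type, 0 to 1 in the other label and 0 to 431 for the difference. Lists that reversed ran from -0.3239 to 0.6571 (macrophage) and -2.72 to 0.4818 (skeletal muscle) for HDL in arteries labelled Atf3-deficient, -2.961 to 0.2565 (skeletal muscle, difference), and -0.1764 to 0.1582 (reticulum chaperones) and -0.1472 to 0.5288 (antigen presentation) between the labels with PBS.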

Other observations

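The test of the genes nearest to Atf3 was chosen only after the result was seen. Lysosomal genes passed as a list with HDL under both ligands, though most of them did not pass singly. Of 16, 5 passed upwards and 0 downwards with CpG in wild-type cells of the second experiment (6 and 0 adjusted over the list alone, median 0.23, adjusted p = 0.00126). With P3C 5 and 0 did, by either count (adjusted p = 0.0181). In cells labelled Atf3-deficient 4 and 0 did with P3C (5 and 0 adjusted over the list alone, adjusted p = 0.000512). With CpG in those cells 5 passed upwards and 0 downwards, by either count (adjusted p = 0.0468, adjusted p = 0.0808 with an estimated correlation). In the first experiment 2 and 0 did, by either count (adjusted p = 0.0117, adjusted p = 0.16 with an estimated correlation). There Lipa, the acid lipase that frees cholesterol from lipoproteins, rose by 0.87 ± 0.17 with HDL before CpG. Of 14 macrophage and monocyte markers, 3 fell with HDL alone in wild-type and 3 in cells labelled Atf3-deficient, led by the fractalkine receptor Cx3cr1, with 0 rising in each and 11 not passing (5 and 4 down adjusted over the list alone; medians -0.33 and -0.24, adjusted p = 4.99e-05 and 0.00735). In the first experiment 4 fell and 0 rose (0 up and 4 down adjusted over the list alone; median -0.07, adjusted p = 0.0163; adjusted p = 0.183 with an estimated correlation), and with the chip in the model the median was -0.33. Cell cycle genes fell with HDL in cells labelled Atf3-deficient too, 12 of 21 with 0 rising (13 down adjusted over the list alone; median -0.70, adjusted p = 1.68e-09).

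Ligands alone moved other groups in wild-type cells of the second experiment. Genes of the metallothionein and hypoxia list rose in 8 of 14 cases with CpG and 9 with P3C and fell in 0 and 1 (8 up and 1 down, and 9 up and 1 down, adjusted over the list alone; adjusted p = 0.00287 and 0.00418; adjusted p = 0.0766 and 0.0896 with an estimated correlation). Of 5 granulocyte markers, which include antimicrobial genes that macrophages also express, 4 rose with each ligand and 0 fell, by either count (medians 1.41 and 1.10, adjusted p = 0.00371 and 0.0117; adjusted p = 0.0571 for P3C with an estimated correlation). LXR targets and genes of cholesterol efflux had medians of -0.02 with HDL and 0.23 with HDL before CpG and did not pass as a list (adjusted p = 0.968 and 0.18), although Abcg1 fell in each of these comparisons. Over the 6 treatments the median excess of interferon-stimulated genes in cells labelled Atf3-deficient was 2.28 in control, 1.33 with CpG, 1.0 with P3C, 1.12 with HDL, 1.44 with HDL and CpG and 1.11 with HDL and P3C.

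Erdr1, a gene whose copies lie at the end of the sex chromosomes, parted the labels in macrophages: its log2 signal was 10.83 to 12.04 on the 18 wild-type arrays of the second experiment and 4.31 to 4.98 on the 18 arrays labelled Atf3-deficient. In the artery 10 of 12 arrays followed their labels, while HDL replicate 3 of the arteries labelled Atf3-deficient was at 10.33 and wild-type PBS replicate 3 at 4.48, and the second probe gave 6.56 and 4.32; these arrays lie beside each other on the same chip. A difference between the mouse lines that does not depend on the tissue may account for it, since the mean difference in the artery was -4.11 ± 1.21 (limma, adjusted p = 0.996). Whether these 2 arrays were exchanged could not be decided: a score over 252 genes that parted the labels in macrophages gave -0.05 between the labels as given and -0.11 with both exchanged, and of 36 possible exchanges 27 gave a higher difference than that of these 2, up to 0.18. The score is of no use here because it does not part the arteries even under the labels as given.

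DNA of another strain kept around the targeted gene could raise the share of its neighbours that differ between the labels. Over the 62 tested genes around Atf3 that share was not raised in control cells. Of the 50 tested genes before Atf3 in the reference order and the 12 after it, 8 of 62 (12.9%) differed between the labels, beside 1213 of 9141 others (13.27%; 2-sided Fisher's exact test, p = 1). These 62 genes are few beside the 1222 that differed, so the test cannot say how many of all differences such DNA accounts for. DNA kept farther away was not tested, and for the nearest genes kept DNA stays open. With 12 on each side 5 of 24 (20.83%) differed, beside 13.25% (2-sided Fisher's exact test, p = 0.238). They include Batf3 (-0.984, adjusted p = 0.00369) and Flvcr1 (-1.174, adjusted p = 9.37e-07), the first and second before Atf3, and Ints7 (-0.6337, adjusted p = 0.00142), the second after it. In the artery 4 of the 7 called neighbours tested there had the same sign, 1 of them, Ints7 (-0.6412), with an unadjusted limma p under 0.05.

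Sex-linked transcripts set the experiments apart. Xist, which is expressed from an inactive X chromosome, was detected on 0 of 12 arrays of the first experiment, 36 of 36 of the second (median log2 signals of 11.05 and 11.32 for the 2 strongest probes) and 12 of 12 artery arrays (10.34 and 10.56), while a probe for the Y-linked gene Eif2s3y was detected on 12, 0 and 0, one for Kdm5d on 12, 0 and 0 and one for Uty on 12, 10 and 0. The design text describes the mice of the artery experiment as male, although Xist was detected on all 12 of those arrays.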
